A study of Homo sapiens with 14 samples.

How the data were processed

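The series held 14 samples of chromatin immunoprecipitation sequencing from the BE2C and Kelly neuroblastoma lines. Peak lists of 11 were used: MYCN, HAND2, ISL1, GATA3 and TBX2 in each line and H3K27ac in BE2C. The 3 input libraries came with no processed file here and were not used. Per the labels, the H3K27ac list combines 2 libraries, and Kelly MYCN and Kelly TBX2 belong to a second batch. Samples were grouped by target and line from their titles, which gave 1 library per group, so no test between libraries of a group could be made and no value has a spread between replicates.

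Reads were aligned with Bowtie to hg19 and factor peaks were called with MACS 1.4, per the submitters' processing notes. Peak names in the files carry the caller's prefix. Each factor file holds the peaks of 1 library. The control library and the call parameters are not given in the sources used here. The fifth column is the peak score as the authors deposited it, a number from 90.0 upward that has the range of minus 10 times the log10 of the caller's p, and it is not comparable between libraries. The H3K27ac file holds the chromosome, start and end of each region as the authors deposited them, with no score, and how those regions were called and joined is not given in the sources used here. A list with a lower depth has fewer called peaks, and depth cannot be read from peak lists, so the number of peaks does not measure the amount of binding and a peak missing from 1 list may lie just under the caller's threshold. The peak numbers of the BE2C HAND2 file run to 43308 with 1 number missing; in the other 9 factor files they are complete.

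Coordinates are hg19, written 1-based. The gene table at hand was of another build, so no gene, promoter or motif was assigned to a peak, and no coordinate was converted. The planned shares of promoter peaks, tests of gene lists and motif shares, and repeats restricted to peaks far from promoters, were therefore not run. The chromosome length used for placement was the largest end coordinate over all lists.

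Peaks overlapped when they shared at least 1 bp. Shares have exact (Clopper-Pearson) 95% intervals. Overlap was tested against 1000 random placements of 1 list, each peak keeping its width and chromosome, and the p-values are two-sided with Benjamini-Hochberg adjustment within a family (5 factors, or 20 pairs). The match of factors between lines was tested by an exact permutation of all 120 pairings of the Kelly with the BE2C lists on the mean log2 Jaccard index. Merged sites were made by joining overlapping peaks of the 5 factors of a line; the count with all 5 was set against 1000 placements of the 5 lists. The trend of H3K27ac or of presence in the other line with the number of factors was tested with 100000 permutations of the numbers over the sites. Sites are not independent of their neighbours, so these trend p-values are too small. Differences between shares have intervals and p-values from 1000 resamples of 5 Mb genome blocks; these treat each list as fixed and carry no error between libraries. H3K27ac regions within 12 kb were joined into stitched regions.

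Places named in the report followed a rule set before the data were examined: the 15 stitched regions with the most 5-factor sites (ties by length), the 8 sites per line with all 5 factors and no peak of the other line within 5 kb that had the highest ranks, and the 3 highest-scoring peaks of each list. Equal scores were ordered by width and then position to choose peaks, and shared their mean rank in rank correlations. Many peaks share the score 3100 near the top of the range (2434 in BE2C HAND2 and 2302 in BE2C ISL1, with 145 and 122 above it). The 2000 highest-scoring peaks of these 2 lists therefore depend on that rule. So does the order of the first BE2C ISL1 and Kelly HAND2 peaks, tied on 3233.06, and of the first Kelly MYCN peaks, tied on 3230.05. The text gives some leading members of each set by position and describes the rest by counts. The wide places outside the BE2C H3K27ac regions in the closing observations were chosen after their values were seen. The tests of shared peaks, factor pairs, 5-factor sites, the match of factors and H3K27ac overlap with its trend were also set before the data were examined. So were their alternatives (5000 or 2000 highest-scoring peaks per list, an overlap of at least 50% of the shorter peak, midpoints within 500 bp, 400 bp around the midpoint, placement within H3K27ac regions, and no second-batch factors). Moving peaks by 10 to 100 kb, leaving out ISL1, splitting sites by MYCN, and midpoints for the trend with the other line were added later. The plan did not hold the trend with presence in the other line or the comparison of the longest stitched regions with the rest. Nor did it hold the resampled differences in pair overlap between lines and in H3K27ac share between MYCN and other factors.

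The procedures were tested on simulated data. For GATA3, with 17996 BE2C peaks, random lists with no planted overlap were called in 0 of 40 simulations, and lists with 200 planted shared peaks in 40 of 40, with a mean excess of 199 peaks over placement. These lists were placed uniformly, as in the test itself, so the result checks the procedure and not false calls where real peaks cluster. All 200 planted sites with 5 factors were found. Block resampling covered a known difference in 96 of 100 simulations. The trend test called 1 of 40 simulations with no trend and 40 of 40 with a trend of 2 points per factor. Its simulated sites were independent, unlike real neighbouring sites. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.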

Results

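Binding of 5 transcription factors was mapped by chromatin immunoprecipitation followed by sequencing in BE2C and Kelly, 2 established human cell lines of neuroblastoma, a childhood tumour of the sympathetic nervous system. The series title describes the tumours modelled here as carrying extra copies of the MYCN gene. The factors were MYCN, a MYC family protein that binds DNA as a partner of MAX, HAND2, a basic helix-loop-helix factor of sympathetic neuron development, ISL1, a LIM homeodomain factor, GATA3, a zinc finger factor needed for sympathetic neurons, and TBX2, a T-box factor. Acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was mapped in BE2C only. The title names a core regulatory circuitry driven by super-enhancers, that is, a set of factors that bind together at long, heavily acetylated enhancers, and the questions taken up here were whether the 5 factors occupied the same places, whether those places carried H3K27ac, and whether they were shared between the lines.

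There was 1 library for each factor and line and 1 list of H3K27ac regions, made from 2 combined libraries, so no value has a replicate. The peak lists carried no read counts and the depth of the libraries is unknown. Intervals are 95% intervals and cover counting error or genome position only, not the error between libraries. Scores are those of the authors' peak caller and were used only to rank peaks within a list. Positions are 1-based on hg19, and no gene annotation of that build was used, so places are given by coordinates alone.

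The lists differed widely in length. HAND2 had 43307 peaks in BE2C and 28910 in Kelly, MYCN had 15716 and 34008, GATA3 had 17996 and 14961, and TBX2 had 14199 and 15751. ISL1 differed most, with 33099 peaks in BE2C and 6905 in Kelly. Median widths ran from 554 bp for BE2C MYCN to 942 bp for BE2C ISL1. The BE2C H3K27ac list held 33142 regions with a median width of 1682 bp, covering 67.5 Mb. Each factor was precipitated with the same antibody catalogue number and lot in both lines, per the labels. Kelly MYCN and Kelly TBX2 carried a second-batch label, and the other run identifiers also separated the lines, so line and batch cannot be told apart in any comparison of BE2C with Kelly.

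Each factor returned to many of the same places in the other line. Of the BE2C MYCN peaks, 67.6% overlapped a Kelly MYCN peak (95% interval 66.9 to 68.3%), as did 44.4% for HAND2, 44.4% for TBX2, 38.1% for GATA3 and 17.8% for ISL1. In the other direction 87.9% of the Kelly ISL1 peaks, 68.0% of the Kelly HAND2 peaks, 45.9% for GATA3, 40.8% for TBX2 and 30.7% for MYCN overlapped the BE2C list of the same factor. The low value for BE2C ISL1 and for Kelly MYCN fell on the longer list of each pair, and the order of the factors depended on list length. With the 5000 highest-scoring peaks of each list the shares of BE2C peaks were 53.8% for HAND2, 50.9% for ISL1, 41.5% for GATA3, 39.0% for TBX2 and 38.0% for MYCN. In each of the 10 lists strong peaks were shared more often than weak ones. In the top 10% of BE2C ISL1 peaks by score 65.5% had a Kelly ISL1 peak, against 2.27% in the bottom 10%, and for BE2C HAND2 the values were 89.7% and 19.7%. Random placement of the Kelly peaks on their own chromosomes gave an overlap of 0.431 to 1.75% of BE2C peaks, and each factor exceeded all 1000 placements (two-sided permutation p = 0.002, the smallest they can give; adjusted p = 0.002 over 5 factors). The excess over placement was 25.3 to 51.2 times. It shrank to 2.39 times for MYCN, 2.52 for HAND2, 3.78 for TBX2, 4.41 for GATA3 and 4.94 for ISL1 when peaks in the BE2C H3K27ac regions were placed within those regions only, and all 5 still passed. With peaks moved by 10 to 100 kb, an alternative chosen after seeing the data, it was 12.4 to 26.3 times.

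Lists of the same factor were on average more alike across lines than lists of different factors, though not for each factor. With the 5000 highest-scoring peaks of each list, the mean log2 Jaccard index (base pairs shared over base pairs covered by either list) was -2.10 for lists of the same factor and -2.90 for lists of different factors, a difference of 0.79. Of the 120 pairings of Kelly with BE2C lists, 2 scored as high, the true one included (exact permutation test, one-sided p = 0.0167, where 0.00833 is the smallest possible). The BE2C MYCN, HAND2 and GATA3 lists each matched their own Kelly list best, whereas BE2C ISL1 and BE2C TBX2 both matched Kelly GATA3 best. From the Kelly side, MYCN, HAND2 and TBX2 matched their own BE2C list best. Kelly GATA3 and Kelly ISL1 both matched BE2C TBX2 best (log2 Jaccard -1.83 and -1.98, against -2.02 and -2.13 with their own factor). Only MYCN and HAND2 thus matched best in both directions. By share of peaks in place of base pairs 4 of 5 BE2C lists matched best, because BE2C ISL1 then overlapped Kelly ISL1 (51.8%) slightly more than Kelly GATA3 (51.6%). Kelly GATA3 still overlapped BE2C ISL1 (51.6%), TBX2 (47.6%) and HAND2 (43.3%) more than BE2C GATA3 (41.6%). With the full lists the difference was 0.40, 3 of 5 BE2C lists matched best and 5 of 120 pairings scored as high (exact permutation p = 0.0417). MYCN stood furthest from the rest: 37.8% of its peaks overlapped between lines, against 9.46 to 14.9% for Kelly MYCN with the other BE2C lists and 22.2 to 26.2% for BE2C MYCN with the other Kelly lists. Without MYCN and TBX2, whose Kelly libraries came from the second batch, the difference was 0.47 and 2 of 6 pairings were as high (exact permutation p = 0.333, smallest possible 0.167). This design is too small to reach 0.05, and the exchange of ISL1 with GATA3 again scored higher than the true pairing.

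**Figure D1:**
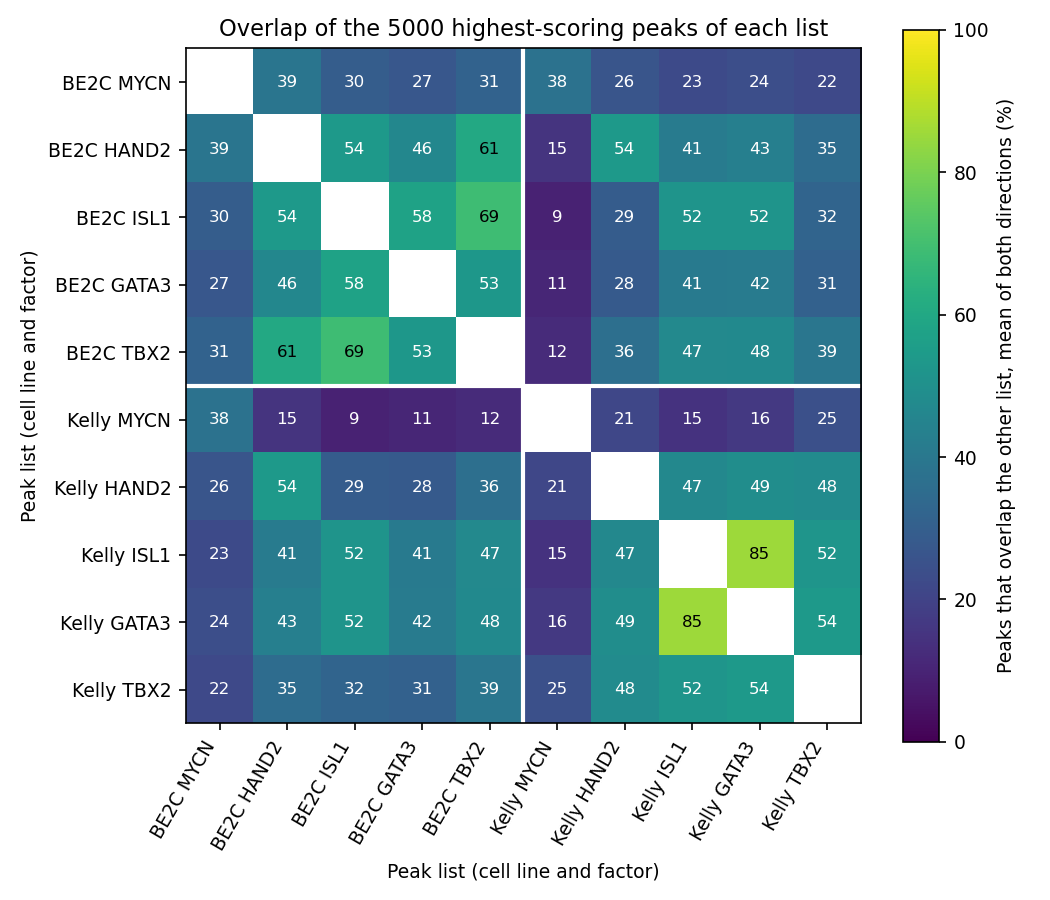
Each cell gives the percent of the 5000 highest-scoring peaks of a list (row) that overlap those of another list (column), as the mean of both directions, for 5 factors in BE2C and Kelly. Kelly ISL1 with Kelly GATA3 is the highest cell (85.3%), and Kelly MYCN has low overlap with the BE2C lists other than MYCN (9.46 to 14.9%).

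Within each line the peaks of the factors fell at many of the same places. In BE2C 91.2% of the TBX2 peaks, 77.5% of the GATA3 peaks, 71.9% of the ISL1 peaks and 67.6% of the MYCN peaks overlapped a HAND2 peak, the longest list of that line. In Kelly 97.4% of the ISL1 peaks overlapped a GATA3 peak and 85.3% a HAND2 peak, and 73.3% of the TBX2 peaks overlapped a MYCN peak. Peak lists of separate libraries cannot show for any pair that both factors were bound together, and no placement was matched to open chromatin outside H3K27ac regions. The Kelly ISL1 list lay almost wholly in that of GATA3. The values with Kelly ISL1 above, here and below therefore carry the further doubt whether ISL1 itself was bound there. Overlap of the 10 pairs was 24.0 to 55.0 times that of random placements in BE2C and 27.2 to 128 times in Kelly (27.2 to 76.1 times for the Kelly pairs without ISL1). All 20 pairs exceeded all 1000 placements (two-sided permutation p = 0.002, the smallest they can give; adjusted p = 0.002). When placement was restricted to peaks inside the BE2C H3K27ac regions and to the space within those regions, the excess shrank to 2.29 to 4.60 times in BE2C and 1.93 to 10.3 times in Kelly, and all 20 pairs still passed. With peaks moved by 10 to 100 kb, the excess was at most 24.7 times in BE2C and 13.4 to 53.0 times in Kelly.

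With list length held at 5000 peaks, MYCN was the outer member of the group in both lines by share of peaks. The excess over placement with the full lists did not set it apart in BE2C (26.2 to 52.4 times with MYCN, 24.0 to 55.0 without). In Kelly it did (27.2 to 41.2 times with MYCN, 45.7 to 128 without). At 5000 peaks the overlap of MYCN with the other factors was 27.1 to 38.8% in BE2C and 14.8 to 24.6% in Kelly, whereas pairs among HAND2, ISL1, GATA3 and TBX2 reached 46.5 to 69.0% in BE2C and 46.8 to 54.1% in Kelly, apart from 85.3% for Kelly ISL1 with GATA3, the pair in doubt. The closest pair was ISL1 with TBX2 in BE2C (69.0%, block bootstrap interval 67.9 to 70.2%) and ISL1 with GATA3 in Kelly (85.3%, 84.5 to 86.0%). In Kelly minus BE2C terms, ISL1 with GATA3 differed by 27.4 points (26.0 to 29.0 in resampled 5 Mb blocks) and ISL1 with TBX2 by -16.8 points (-18.5 to -15.3). The 4 MYCN pairs differed by -17.5 to -6.80 points. GATA3 with TBX2 was 52.8% in BE2C and 54.1% in Kelly, a difference of 1.26 points whose interval held 0 (-0.430 to 2.98), and it was the only pair of 10 that did not pass after Benjamini-Hochberg adjustment. The Kelly library of MYCN or TBX2 in these pairs came from another batch than its Kelly partner, except for MYCN with TBX2. A cut at 5000 peaks also takes a larger part of a short list, such as Kelly ISL1, than of a long one. Measured as excess over placement at 5000 peaks, ISL1 with TBX2 went the other way (129 times in BE2C, 179 in Kelly). So did HAND2 with ISL1 (94.5 and 116 times), whereas the other pairs kept their direction.

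Places with peaks of all 5 factors were numerous. Joining overlapping peaks of the 5 factors gave 60149 sites in BE2C, of which 4077 (6.78%) held all 5, and 51400 in Kelly, of which 4000 (7.78%) did. The Kelly 5-factor sites rest on the ISL1 list that lies almost wholly in the GATA3 list, with the doubt given above. No random placement of the 5 lists gave more than 1 such site in either line (permutation p = 0.002, the smallest 1000 placements can give). With peaks moved by 10 to 100 kb, a later alternative, placements gave at most 10 such sites in BE2C and 5 in Kelly. The lists were placed independently of each other, so after the overlap of the pairs above this test adds little. No placement within H3K27ac regions was made for this count. HAND2 alone was the most frequent makeup in BE2C (14450 sites), followed by ISL1 alone (7636), HAND2 with ISL1 (6820), MYCN alone (4625) and then all 5. In Kelly MYCN alone led (15426 sites), then HAND2 alone (10125) and MYCN with HAND2 (4475). Without ISL1, the shortest Kelly list, 6367 Kelly sites held the other 4 factors, against 4119 in BE2C, an alternative chosen after seeing the data.

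The more factors a site held, the more often it was bound in the other line. A Kelly peak of any factor overlapped 38.8% of the BE2C sites with 1 factor, 43.2% with 2, 54.4% with 3, 68.7% with 4 and 83.7% with 5. For Kelly sites the share with a BE2C peak rose from 42.1% with 1 factor to 94.6% with 5. Both trends passed a permutation test of the number of factors over the sites (two-sided p = 2e-05, the smallest 100000 permutations can give). That test was not in the plan. Sites with more factors were also wider, with a median of 713 bp for 1 factor and 1628 bp for 5 in BE2C, and the trends passed equally with site midpoints in place of whole sites. Strong peaks were shared between lines more often than weak ones, and sites were not matched for peak rank. The trends therefore do not separate the number of factors from peak strength. Of the 4077 sites with all 5 factors in BE2C, 1683 (41.3%, 39.8 to 42.8%) overlapped a Kelly site that also held all 5.

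**Figure D2:**
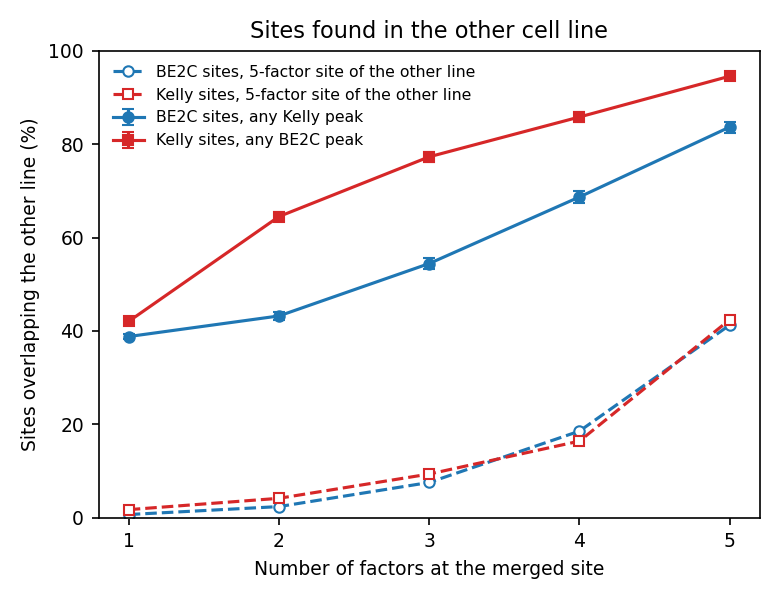
Percent of merged sites (vertical axis) that overlap a peak of any factor in the other line (solid lines, bars are exact 95% intervals) or a site of the other line with all 5 factors (dashed lines), by the number of factors at the site (horizontal axis), for BE2C and Kelly. The solid lines climb from 38.8 to 83.7% in BE2C and from 42.1 to 94.6% in Kelly.

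A minority of the 5-factor sites had no called peak nearby in the other line. In BE2C 550 of them (13.5%, 12.5 to 14.6%) had no Kelly peak of any factor within 5 kb, and 43.6% of these overlapped a BE2C H3K27ac region. In Kelly 186 (4.65%, 4.02 to 5.35%) had no BE2C peak within 5 kb, and 8 of these (4.30%) overlapped a BE2C H3K27ac region. The BE2C examples with the highest mean rank of the 5 peaks within their lists lay on chromosome 7 from 107930398 to 107933150, on chromosome 4 from 95284334 to 95286620 and on chromosome 7 from 16272248 to 16277321, and the 8 highest all overlapped H3K27ac. The highest-ranked Kelly examples lay on chromosome 12 from 11584622 to 11587619 and from 128908819 to 128910843 and on chromosome 3 from 55654032 to 55655652, and none of the 8 highest overlapped a BE2C H3K27ac region. H3K27ac of Kelly was not analysed here.

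MYCN was the factor most often found on H3K27ac chromatin. In BE2C 62.3% of the MYCN peaks overlapped an H3K27ac region (61.5 to 63.1%), against 40.2% of the TBX2 peaks, 32.1% for HAND2, 31.8% for GATA3 and 24.3% for ISL1. Random placement gave 2.94 to 3.28%, and each factor exceeded all 1000 placements (two-sided permutation p = 0.002, the smallest they can give; adjusted p = 0.002 over 5 factors). Peaks moved by only 10 to 100 kb met the mark in 5.36 to 7.48% of cases, which lowered the excess from 7.68 to 20.1 times to 4.54 to 8.32 times. MYCN exceeded the other factors by 22.0 points (over TBX2, 20.8 to 23.3) to 38.0 points (over ISL1, 36.8 to 39.1) in resampled 5 Mb blocks. Among the 5000 highest-scoring peaks the MYCN value was 72.2% and those of the others 42.8 to 53.5%. Seen from the mark, 53.2% of the 33142 H3K27ac regions held a peak of at least 1 factor, with HAND2 in 39.4%, MYCN in 28.8%, ISL1 in 23.6%, TBX2 in 17.4% and GATA3 in 16.9%.

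With MYCN counted as 1 of the factors, the number of factors at a site and H3K27ac went together over all BE2C sites. Among the sites that held MYCN they did not. The share of sites on H3K27ac was 28.0% with 1 factor, 29.8% with 2, 30.0% with 3, 34.6% with 4 and 54.9% with 5. Sites on H3K27ac held a mean of 2.26 factors and other sites 1.93 (permutation p = 2e-05, two-sided, the smallest 100000 permutations can give). This count includes MYCN itself, and each site with all 5 factors holds MYCN by definition. Sites with a MYCN peak lay on H3K27ac in 62.1% of cases and sites without one in 20.6%. The trend over all sites therefore does not separate the number of factors from the presence of MYCN. Splitting the sites by MYCN, a choice made after seeing the data, changed the picture. Sites with a MYCN peak lay on H3K27ac in 70.1% of cases when MYCN was alone, 65.6% with 1 other factor, 59.8% with 2, 55.9% with 3 and 54.9% with all 4 (permutation p = 2e-05). Sites without MYCN stayed between 19.8 and 23.2% at any number of factors, with a small rise over the number of factors that passed the same test. HAND2, ISL1, GATA3 and TBX2 together without MYCN marked 3785 sites, 23.2% of them on H3K27ac, against 54.9% of the 4077 sites that also held MYCN. ISL1 alone was on H3K27ac at 7.08% of its 7636 sites and TBX2 alone at 51.2% of its 531.

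**Figure D3:**
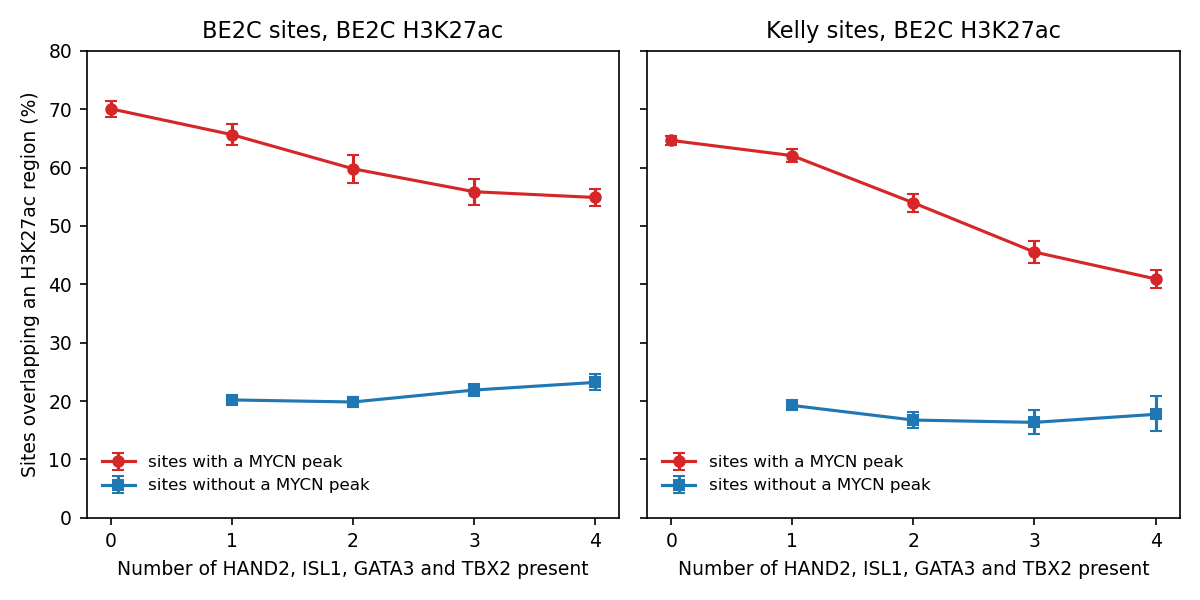
Percent of merged sites that overlap a BE2C H3K27ac region (vertical axis, exact 95% intervals) by how many of HAND2, ISL1, GATA3 and TBX2 they hold (horizontal axis), for sites with and without a MYCN peak in BE2C (left) and Kelly (right, the mark being from the other line). Sites with MYCN fall from 70.1 to 54.9% in BE2C and from 64.6 to 40.9% in Kelly, and sites without MYCN stay at 16.4 to 23.2% in the 2 lines.

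Set beside the BE2C mark with no placement test, the Kelly lists gave the same order for MYCN. Of the Kelly MYCN peaks 58.3% overlapped a BE2C H3K27ac region, and 88.2% of its 5000 highest-scoring peaks did. The other Kelly factors had 32.5 to 42.8% on the mark over the full lists and 34.4 to 45.3% among 5000 peaks. Over all Kelly sites the share on the BE2C mark was 43.8% with 1 factor, 48.8% with 2, 44.3% with 3, 40.6% with 4 and 40.9% with 5, unlike the rise in BE2C. The mean number of factors at Kelly sites on the mark minus that at other sites was -0.0412 (two-sided permutation p = 0.0003), -0.0477 among sites without MYCN (p = 0.00124) and -0.492 other factors among sites with MYCN (p = 2e-05, the smallest possible), in tests not planned for Kelly.

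Many scores pile up near the top of the range, with 2434 BE2C HAND2, 2302 BE2C ISL1 and 1211 Kelly HAND2 peaks tied on 3100. In these lists 145, 122 and 91 peaks lay above it, up to 3233.06. Apart from BE2C MYCN, whose first peak scored 3100 and the next 1909, first peaks are examples among close scores. They are not shown to be the strongest places of a list. For MYCN, with 1 BE2C and 155 Kelly peaks on 3100, the first was on chromosome 7 from 807024 to 808575 in BE2C and on chromosome 19 from 5790364 to 5791646 in Kelly, both on BE2C H3K27ac regions. The first Kelly ISL1 peak (chromosome 7, 85138952 to 85140484), BE2C GATA3 peak (chromosome 4, 151628879 to 151629981) and BE2C TBX2 peak (chromosome 1, 197651344 to 197654248) each lay at a peak of all 10 lists, whereas the first peaks of BE2C MYCN, BE2C ISL1 and Kelly GATA3 met 4 other lists and that of Kelly MYCN met 2. Of the 30 peaks taken, 3 per list, 16 lay at a peak of all 10 lists and 18 on BE2C H3K27ac regions, counts that describe these examples alone.

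Long H3K27ac regions, the closest measure here to super-enhancers, often held 5-factor sites. Regions within 12 kb of each other were joined into 20006 stitched regions, ranked by length because the file has no signal. A 5-factor site lay in 1897 of them (9.48%). Among the longest 5% (1001 regions of at least 22.6 kb) 31.8% held one (28.9 to 34.8%), against 8.31% of the rest (7.92 to 8.71%). Per unit of stitched length the order was the other way, with 1.46 sites per 100 kb of the longest regions and 2.17 per 100 kb of the rest. Each factor alone showed the same order, for example MYCN with 5.95 and 9.86 peaks per 100 kb. Stitched length includes unmarked gaps of up to 12 kb. A site also counted with 1 bp of overlap, which adds more to short regions. These densities therefore do not show fewer sites per length of marked chromatin in long regions.

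The stitched region with the most 5-factor sites spanned 130 kb of chromosome 1, from 216671284 to 216801565, with 21 H3K27ac regions, 7 sites with all 5 factors in BE2C and 5 in Kelly. It held 23 ISL1, 20 GATA3, 19 HAND2, 14 TBX2 and 9 MYCN peaks in BE2C. On chromosome 4 the regions from 175112854 to 175222405 and from 96429650 to 96478254 held 6 such sites each in BE2C, and 5 and 7 in Kelly. Chromosome 1 from 162847319 to 162917453 held 5 in BE2C and 6 in Kelly, chromosome 3 from 159536171 to 159604445 held 5 and 2, and chromosome 14 from 35988536 to 36050415 held 5 and 3. The other 9 of the 15 leading regions held 4 each in BE2C. Of the 15, 13 had a 5-factor site in Kelly as well. The exceptions were chromosome 6 from 126130626 to 126192654 and chromosome 9 from 97625873 to 97686703, where Kelly had no TBX2 peak and, in the latter, no ISL1 peak.

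**Figure D4:**
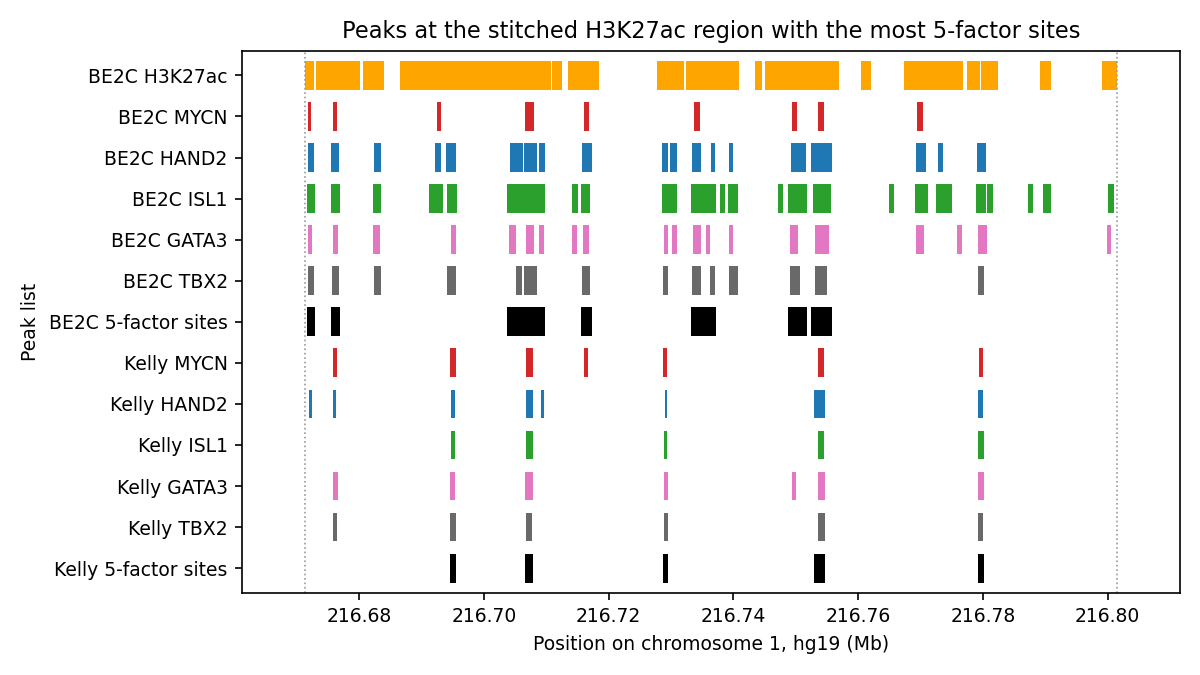
Peaks of the 5 factors in BE2C and Kelly, BE2C H3K27ac regions and merged sites with all 5 factors, drawn to scale along chromosome 1 of hg19 (Mb), with dotted lines at 216671284 and 216801565, the ends of the stitched region. BE2C has 7 sites with all 5 factors between these lines and Kelly has 5.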

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

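Of the tests in this part, the one on Kelly ISL1 peaks outside the GATA3 list, the one on peak scores, the one on the 5000 highest-scoring MYCN peaks and the one on sites with MYCN alone were chosen after the result was seen. The comparison of pair overlap between the lines was not in the original plan.

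The overlap of 9 of the 10 factor pairs differed between the lines when the blocks of the genome were resampled, with 5000 peaks per list. Kelly minus BE2C was -17.5 points for MYCN with HAND2, -14.8 for MYCN with ISL1, -10.7 for MYCN with GATA3, -6.80 for MYCN with TBX2, -7.07 for HAND2 with ISL1, 2.52 for HAND2 with GATA3, -12.4 for HAND2 with TBX2, 27.4 for ISL1 with GATA3 and -16.8 for ISL1 with TBX2. The resampling carries no error between libraries, and line and batch cannot be told apart. By excess over placement at 5000 peaks, HAND2 with ISL1 and ISL1 with TBX2 differed in the other direction, as given above.

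In Kelly, ISL1 and GATA3 were nearly the same list: 97.4% of the ISL1 peaks lay in the GATA3 list. List length moves this share, since BE2C ISL1 lay in BE2C GATA3 at 40.4% over the full list and 83.3% (82.4 to 84.1%) at the 6905 strongest peaks, but the other Kelly lists shortened alike gave at most 77.2% (TBX2; upper bound 78.2%), which argues against length as the whole reason. A repeat of the GATA3 precipitate stays open: a test on rank differences between the lines gave a rho of 0.0582 (0.0251 to 0.0907), on both sides of the 0.05 set for it, where other pairs gave 0.0424 (TBX2 with GATA3), 0.363 (HAND2 with GATA3), 0.367 (MYCN with GATA3) and 0.560 (HAND2 with TBX2). Of the 54 Kelly ISL1 peaks outside the GATA3 list that overlapped only 1 of the BE2C ISL1 and GATA3 lists at equal length, 81.5% (68.6 to 90.7%) overlapped ISL1, against 62.6% (60.4 to 64.9%) for Kelly GATA3 peaks outside the ISL1 list, but these sets were selected on the lists in question and do not settle it. Scores of overlapping ISL1 and GATA3 peaks had a rho of 0.853 (0.843 to 0.862; 0.624 for the next pair of lists), known before that test was set, and a repeat, GATA3-bound DNA mixed into a weak ISL1 library and close binding of both factors could each give it, so these cannot be told apart.

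BE2C sites with a MYCN peak lay on H3K27ac far more often than sites without one. Matching sites by width left a difference of 29.4 points (28.2 to 30.8) in midpoints on the mark, and MYCN exceeded HAND2, the next factor, by 18.7 points (17.0 to 20.4) among 5000 peaks of each list, which argues against width and against peak rank as the reason. Background capture of active chromatin in the MYCN library was not excluded: sites with MYCN alone were marked at 70.1% (68.7 to 71.4%) and 5-factor sites at 54.9%, values known before that test was set, which binding of MYCN at active promoters would give too. Both stay open, because promoters were not assigned and the input libraries were not used.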

How the results depend on the processing

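Peaks moved by 10 to 100 kb, sites split by MYCN, lists without ISL1 and midpoints for the trend with the other line were chosen after the results were seen. Of 143 alternative values, 138 kept their direction and their side of the threshold or stayed within 1.5 times, among them all 80 for single factor pairs. Each placement test gave the smallest possible permutation p (0.002) in all settings, so this count is a weak check of those results. Sizes moved within that, as the report gives for shares between lines with 5000 peaks, for placement within H3K27ac regions and for locally moved peaks. The trend of H3K27ac with the number of factors had the other sign at BE2C sites with MYCN. There sites on the mark held -0.434 other factors relative to those off it, against 0.323 factors for all sites. At BE2C sites without MYCN the value was 0.0514. The value for all sites counts MYCN itself, whereas the split values count only the other 4 factors, so they are unlike measures. Sites with a MYCN peak were marked at 62.1% and sites without one at 20.6%, which enters the value for all sites. The cause of the fall among sites with MYCN was not tested. The match of factors between lines no longer passed without the second-batch factors (0.47 on the log2 scale, where 6 pairings cannot reach 0.05). Apart from that limit, the exchange of ISL1 with GATA3 scored higher there than the true pairing. With 5000 peaks per list, 5-factor sites numbered 877 in BE2C and 596 in Kelly, since fewer peaks were used, and without ISL1 the Kelly sites with the other 4 factors numbered 6367. Alternatives restricted to peaks far from promoters, and all planned promoter, gene list and motif results, were not run for want of an annotation or sequence of hg19. No paired analysis was possible because each target and line had 1 library. Depth is unknown, so peaks absent from the shorter lists, such as Kelly ISL1, are not shown to be absent from the cells.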

Other observations

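The tests on chromosomes below were set before their own results were seen, after the pattern itself was noticed.

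Peaks in many lists of both lines did not by themselves place a site on H3K27ac. Joining the 10 lists gave sites held by 1 to 10 lists. The share on the BE2C mark was 29.1% for sites of 1 list, 39.2% for sites of 5 lists and 40.1% for sites of 8 lists, then 44.3% for 9 and 58.4% (56.0 to 60.7%) for the 1684 sites held by all 10. A large part of the places with a peak in all 10 lists therefore lay outside the BE2C regions, though the Kelly ISL1 list is nearly contained in that of GATA3 and does not by itself show ISL1 bound there. Factors on their own differed widely: HAND2 alone was on the mark at 26.7% of 14450 BE2C sites, GATA3 alone at 16.0% of 2451, ISL1 alone at 7.08% and TBX2 alone at 51.2%. HAND2 with TBX2 but no other factor was marked at 44.8% of 513 sites, and HAND2 with ISL1 at 17.6% of 6820.

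A few places with unusually wide peaks recurred outside the BE2C H3K27ac regions. The mark in Kelly was not analysed here. The widest place, of joined peaks, spanned 6041 bp of chromosome 1, from 564367 to 570407, in 5 lists of both lines, and its widest single peak was 6039 bp. Places on chromosome 21 from 11143531 to 11147974, on chromosome 6 from 58775963 to 58780229 and on chromosome 5 from 134259214 to 134264360 were in 4 Kelly lists each and in no BE2C list. Others held nearly all factors in both lines, such as chromosome 17 from 59551193 to 59556872, in 9 of the 10 lists, and chromosome 13 from 107719300 to 107723798, in all 10. These places were chosen after their values were seen. No filter for regions prone to artefact signal was applied to any list here, so such peaks are not shown to mark binding.

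The share of peaks that fell on each chromosome differed between the lines in the same direction for all 5 factors on 19 of 22 autosomes, though the lists of a line share many peaks, so these signs are not independent. The mean log2 ratio of Kelly over BE2C was 0.85 on chromosome 22, 0.64 on chromosome 17, 0.44 on chromosome 19, 0.38 on chromosome 16 and 0.36 on chromosome 1, and -0.71 on chromosome 21, -0.55 on chromosome 13, -0.36 on chromosome 4 and -0.35 on chromosome 9. A library bias toward chromosomes dense in active chromatin would account for part, since the ratio followed the number of H3K27ac regions per Mb over the 22 autosomes (Spearman rho 0.732, Pearson r 0.672, two-sided permutation p = 0.00012 and 0.00053; r 0.637 without the 2 farthest chromosomes), but after a fit on that density 5 chromosomes (1, 5, 18, 21 and 22) kept all 5 factors beyond 0.2 on one side, which argues against it as the whole reason. A difference in chromosome copy number between the lines is a candidate explanation: peaks shared by both lines ranked higher in the line with more peaks on that chromosome (rho 0.941, r 0.949, permutation p = 1e-05, the smallest 100000 permutations can give; r 0.926 without the 2 farthest; 2 relations were computed, adjusted p at most 0.00053). Any other cause that scales the signal of a whole chromosome would give the same, copy number was not measured here, and line and batch cannot be told apart.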
